A study of Homo sapiens with 12 samples.

How the data were processed

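RNA was measured in 12 libraries of myotubes grown from human muscle stem cells: vehicle, MCF-7 CM, MD-468 CM and SKBR-3 CM, 3 libraries each, collected after 36 hours of treatment. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the KAPA mRNA HyperPrep kit. Per the submitters' processing notes, reads were aligned with STAR 2.5.2b to GRCh38 and counted with featureCounts of Subread 1.5.1; the strand setting, the annotation release and the filter on genes are not given in the sources used here. The table the authors deposited holds raw counts per gene and library, log2 FPKM values, and log2 fold changes with p-values for each medium against control. It has 14208 genes, each over 0.5 CPM in at least 3 libraries, and no gene encoded by mitochondrial DNA. The deposited log2 FPKM equal log2 RPKM scaled by TMM factors (median absolute difference 3.8e-04), and they were used for this check only.

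Counts were tested as the authors deposited them in edgeR 4.0.16 (R 4.3.3) with TMM scaling and the quasi-likelihood F test (glmQLFit, glmQLFTest), in 1 fit of all 12 libraries with 7 contrasts: each medium against control, their mean against control, and the 3 pairs of media. filterByExpr removed 0 genes, the common biological coefficient of variation was 0.104, and p-values were adjusted by Benjamini and Hochberg over all genes of a contrast at 0.05. For MCF-7 CM, MD-468 CM and SKBR-3 CM, 4183, 3841 and 2958 genes pass an adjusted p of 0.05 in the authors' deposited table, of which 3634, 3452 and 2421 are called here too; the authors' deposited log2 fold changes differ from those here by at most 0.13, 0.079 and 0.17.

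Depth ran from 25873520 to 46577321 reads per library, and the 10 most abundant genes took 6.28 to 7.16% of the reads. The first principal component of log2 CPM held 44.9% of the variance and the second 24.0%. The procedure was tested on simulated data with the depths and dispersions of these libraries and 200 changed genes per contrast. Of genes changed 1.5-fold it recovered 36 to 51, of 2-fold 56 to 65 (67 of each), and of 4-fold 64 to 66 (of 65 or 66); false calls made up 2.29 to 6.86% of calls. A list shifted 1.5-fold was called in each simulated contrast, with 0 of the 28 other lists. Genes were simulated independently of each other, so this does not test false list calls among correlated genes.

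Gene lists, named genes and contrasts were fixed before the data were examined: 30 lists of muscle, inflammatory, metabolic, matrix and stress genes, 10 lists of cell markers and a panel of 17 genes. Of 941 fixed list members 885 were measured, and the list of genes encoded by mitochondrial DNA had none, which leaves 29 gene lists. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over 203 tests of gene lists and 70 of marker lists. Member counts come from the edgeR calls over all genes, and from p-values adjusted over the list alone. Muscle also expresses many marker genes: at 1 CPM or more in the controls are 3 of 18 measured epithelial markers, 3 of 10 MCF-7 line, 2 of 12 MD-468 line, 7 of 10 SKBR-3 line, 12 of 13 fibroblast, 5 of 8 adipocyte, 9 of 9 smooth muscle, 5 of 6 endothelial, 2 of 3 immune and 2 of 4 neural markers. Other lists hold 6, 4, 2, 4, 3, 0, 4, 1, 0 and 0 of the markers in these lists.

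Genes were named by a fixed rule: the 8 largest rises and 8 largest falls per medium (6 for the mean, 5 per pair of media) with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the libraries of the groups, which chance alone gives in 10% of genes for 3 against 3 libraries and in fewer for the mean of the media. Clone, antisense and pseudogene symbols, HLA genes, X-inactivation genes and Y-linked genes were left out. To these come up to 4 list members with the smallest p per list and the panel. Genes with 0 control reads have their fold given against a floor of 3 reads over the group, and those with 1 to 3 control reads have an exact 95% Poisson interval on the ratio. Symbols are those of the deposited table, some of them older names; reads of close paralogs can be misassigned, and a gene overlapping another on the opposite strand can take its reads where the protocol is unstranded.

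Because each medium is compared with the same controls, overlap, covariance and correlation of changes were set beside 20 simulations of media without effect sharing the controls. Alternatives were RLE scaling, DESeq2 1.42.0, no filter, only the groups compared, the replicate number as a block, each library left out in turn, an estimated correlation and fry (limma) for lists, which asks whether a list moves one way against no change, where camera compares it with other genes; added later were MCF-7 CM by its library 3 alone, 2 libraries per group, genes at 1 CPM or more in controls, and removal of the trend with gene length. Gene length was taken from the authors' deposited table and GC content from the longest GENCODE v29 transcript of each gene. No fit removed the trend with GC content.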

Results

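Human skeletal muscle stem cells were differentiated into myotubes over 7 days and then held for 36 hours in vehicle or in medium conditioned by 1 of 3 breast cancer lines: MCF-7, MD-468 (the name the labels use) or SKBR-3. Each of the 4 groups has 3 RNA-seq libraries. Which mRNAs differ between myotubes in each conditioned medium (CM) and the controls, and which differ between the media, is the question here. Controls have 39572581, 37854319 and 46577321 reads over 14208 genes, and MCF-7 CM libraries 36391905, 26391668 and 38958124. MD-468 CM libraries have 36835038, 35318326 and 25873520 reads, and SKBR-3 CM libraries 30746310, 41470298 and 31275419. The labels number the replicates without saying what a number stands for, so the p-values measure only the spread between these samples, which may be technical. Changes are log2 fold changes from edgeR. The value after ± is the size of the change divided by the square root of its F statistic, an approximate standard error. Group values are mean CPM, reads scaled to library size by TMM.

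Which genes differ between myotubes in MCF-7 CM and in vehicle? Inflammatory genes downstream of NF-kB rose, among them the neutrophil chemokines CXCL1 and CXCL8 and SOD2, the enzyme that clears superoxide in mitochondria. Genes of glycolysis and of the response to low oxygen rose as well, such as PFKFB4, which sets the level of a glycolytic activator, and HILPDA, which restrains fat breakdown in lipid droplets. Amino acid genes driven by ATF4 fell, including PSAT1 of serine synthesis, and so did TGF-beta response genes such as the matrix-linked growth regulator CTGF and the actin ACTA2. The MCF-7 line markers TFF1, a secreted trefoil protein, and KRT8, a keratin, were higher in these libraries and under 1 CPM in the controls, where 3 of the 10 measured markers of that line are expressed.

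In MCF-7 CM 3639 of the 14208 genes (25.6%) passed an adjusted p of 0.05 in edgeR, 1968 higher and 1671 lower (2121 and 2129 with 2 libraries per group). Without control 3 the count was 2238, and without control 2 it was 2250. Changes over 2-fold numbered 540, 423 higher and 117 lower. Of the rises, 260 of the 423 had a control mean under 1 CPM. Across genes, the change in MCF-7 CM falls with GC content (Spearman −0.349). That trend was not removed, so what it adds to the calls and list shifts in this medium is not known. TFF1 rose by 9.39 ± 1.2 (edgeR adjusted p = 9.4e-05), from 0.0777 CPM to 61.4 (SD 47.2). Control reads were 0, 0 and 11 for TFF1 and 0, 0 and 15 for SPTSSB, so these control means rest on control 3. KRT8 rose by 7.20 ± 0.81 (edgeR adjusted p = 3.3e-05), from 0.539 CPM to 82.5 (SD 66.6). Also among the 8 largest rises were SPTSSB (8.48 ± 1.06), a subunit of the enzyme that starts sphingolipid synthesis, and MAL2 (7.10), a protein of apical transport. The transcription factors GATA3 (6.74 ± 0.91) and TFAP2C (6.63) and the adhesion protein CDH1 (6.60 ± 0.83) were too. BMP7, a secreted growth factor, had 3 control reads in all; its ratio of 369.3 has a 95% counting interval of 126 to 1794. Such intervals, and the floors given for genes without control reads, cover counting error only.

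The largest falls in MCF-7 CM included CNN1, a calponin that restrains actomyosin (−2.31 ± 0.14, 11.5 to 2.33 CPM, edgeR adjusted p = 1.4e-07). RELN, a secreted guidance protein, fell nearly as far (−2.28 ± 0.21, 5.11 to 1.04 CPM), ahead of COMP, a matrix protein of tendon and cartilage (−1.65 ± 0.19). TGM2, which crosslinks matrix proteins, went from 157 to 51.1 CPM (−1.62 ± 0.13), and CTGF from 809 to 264 CPM (−1.61 ± 0.13, edgeR adjusted p = 1.1e-06). CHAC1, which degrades glutathione (−1.60), PCK2, which makes phosphoenolpyruvate in mitochondria (−1.59), and ALPK2, a muscle kinase (−1.53 ± 0.07, 98.8 to 34.1 CPM), make up the rest of the 8.

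Of the 37 measured NF-kB targets, 23 rose in MCF-7 CM, 2 fell and 12 did not pass (23 and 2 adjusted over the list alone). SOD2 went from 303 to 1735 CPM (2.52 ± 0.08, edgeR adjusted p = 2.4e-10), the adhesion receptor ICAM1 from 11 to 92.0 CPM (3.07 ± 0.10) and CXCL1 from 0.201 to 15.4 CPM (6.14 ± 0.30). CXCL8 stood at 71.7, 72.3 and 76.9 CPM in the 3 MCF-7 CM libraries, against 2.40, 2.49 and 3.33 in the controls. As a list the NF-kB targets shifted upward (limma camera adjusted p = 2.1e-12, adjusted p = 0.056 with an estimated correlation). The carcinoma transcripts moved upward in the same libraries but unevenly: TFF1 stood at 101, 74.0 and 9.24 CPM and KRT8 at 149, 82.9 and 15.7 CPM.

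Interferon-stimulated genes rose too, 24 of 39 in MCF-7 CM with 0 lower and 15 not passing (25 and 1 adjusted over the list alone). Among them were PARP14, an ADP-ribosyltransferase (1.11, 54.5 to 117 CPM), the antiviral IFIT3 (1.31, 16.6 to 41.3 CPM) and the chemokine CXCL10 (4.04), which stayed low at 0.977 CPM. The list shift had a limma camera adjusted p = 1.3e-07 (adjusted p = 0.43 with an estimated correlation). Over the 24 higher members, the excess over control in MCF-7 CM 2 was a median of 2.08 times that in MCF-7 CM 1 (quartiles 1.70 to 2.57). Glycolysis and hypoxia genes rose in 26 of 34 cases, with 0 lower and 8 not passing (27 and 1 adjusted over the list alone, limma camera adjusted p = 1.1e-16, adjusted p = 0.059 with an estimated correlation). PFKFB4 went from 4.63 to 39.1 CPM (3.08), HILPDA from 6.76 to 40.2 CPM (2.57), BNIP3, a mitophagy receptor, from 110 to 346 CPM (1.66), and the stress gene NDRG1 rose by 1.85. Carcinoma transcripts rose in these same libraries, 17 of 18 epithelial markers being higher.

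ATF4 and amino acid genes fell in 22 of 30 cases in MCF-7 CM, 3 rose and 5 did not pass (4 and 22 adjusted over the list alone, limma camera adjusted p = 1.4e-07, adjusted p = 0.054 with an estimated correlation). PSAT1 went from 103 to 49.7 CPM (−1.05), the cystine importer SLC7A11 fell by 1.14 on the log2 scale, the folate enzyme MTHFD2 changed by −0.92 and the arginine importer SLC7A1 by −0.92. DDIT4, an mTOR inhibitor in the same list, rose by 0.98. TGF-beta response genes were lower in 15 of 27 cases and higher in 2, with 10 not passing (3 and 15 adjusted over the list alone, limma camera adjusted p = 1.4e-05, adjusted p = 0.20 with an estimated correlation). ACTA2, the actin of smooth muscle and myofibroblasts, went from 989.9 to 524.5 CPM (−0.92), the matricellular CYR61 changed by −1.07 and SERPINE1, which blocks plasminogen activation, by −0.91. Smooth muscle markers, 4 of 9 of them held by other lists too, shifted downward with these genes (4 of 9 lower, limma camera adjusted p = 0.019, adjusted p = 0.21 with an estimated correlation, 0.13 with 2 libraries per group), CNN1 among them. CNN1, ACTA2 and TAGLN belong to the TGF-beta list as well, so these list shifts are not separate results.

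Cholesterol synthesis and SREBP targets were lower in 12 of 32 cases in MCF-7 CM and higher in 1, with 19 not passing (2 and 12 adjusted over the list alone, limma camera adjusted p = 0.0024, adjusted p = 0.30 with an estimated correlation). Leading them were the LDL receptor LDLR (−1.30), the mevalonate kinase MVK (−0.82) and the sterol sensor INSIG1 (−0.76). Fatty acid oxidation and PPAR targets rose in 7 of 21 cases, 1 fell and 13 did not pass (9 and 1 adjusted over the list alone, limma camera adjusted p = 0.022, adjusted p = 0.36 with an estimated correlation). The lipid droplet coat protein PLIN2 went from 72.2 to 226 CPM (1.65) and the fatty acid carrier FABP3 rose by 0.48, while the nuclear receptor PPARD fell (−0.65). Without MCF-7 CM 3 this list no longer passed (adjusted p = 0.077 in limma camera). Adipocyte markers shifted upward in the same libraries (3 of 8 higher, limma camera adjusted p = 0.046, adjusted p = 0.21 with an estimated correlation, 0.10 with 2 libraries per group, 0.068 with the length trend removed). Cytosolic ribosomal protein genes shifted upward with 7 of 47 higher, 0 lower and 40 not passing (0 and 0 adjusted over the list alone, limma camera adjusted p = 0.044, adjusted p = 0.86 with an estimated correlation). RPL28 rose by 0.41. For this list the limma camera adjusted p was 0.25 without control 1, 0.086 without control 2, 0.47 without MCF-7 CM 3, 0.051 without MD-468 CM 3 and 0.22 with the trend with gene length removed.

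Muscle lists had no call in MCF-7 CM, though calls appeared in some alternatives. Sarcomere genes rose in 10 of 48 cases and fell in 2 (limma camera adjusted p = 0.18, 0.029 without MCF-7 CM 1), among them KLHL41, which stabilises thin filaments (0.58), LMOD3, an actin nucleator (0.75), and SMYD1, a myosin-directed methyltransferase (0.41). The filament repair protein XIRP1 fell (−0.49). Myogenic regulators rose in 11 of 22 cases and fell in 4 (limma camera adjusted p = 0.21, 0.028 with MCF-7 CM by library 3 alone; 0.016 with fry, which tests a list against no change and not against other genes), with the myogenic factor MYOD1 at 0.66 ± 0.14 (edgeR adjusted p = 0.0044) and the fusion peptide MYMX at 1.25 (12 to 28.6 CPM). Atrophy ligases and FOXO targets (5 of 29 higher, 1 lower, limma camera adjusted p = 0.52, 0.019 with fry) had no list call, and the ligases FBXO32 and TRIM63 did not pass. MSTN, the secreted inhibitor of muscle growth, fell (−1.08), IL6 rose (1.24, 9.46 to 22.45 CPM) and PDK4, which holds pyruvate out of mitochondria, rose (1.37). Unfolded protein response genes were lower in 10 of 22 cases and higher in 1 without a list call (limma camera adjusted p = 0.091), including the chaperone HYOU1 (−0.46) and HERPUD1 of ER-associated degradation (−0.38). That list passed without MCF-7 CM 1 (limma camera adjusted p = 0.042) and with MCF-7 CM by library 3 alone (0.0068). Against no change, in fry, it had 0.023.

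**Figure D1:**
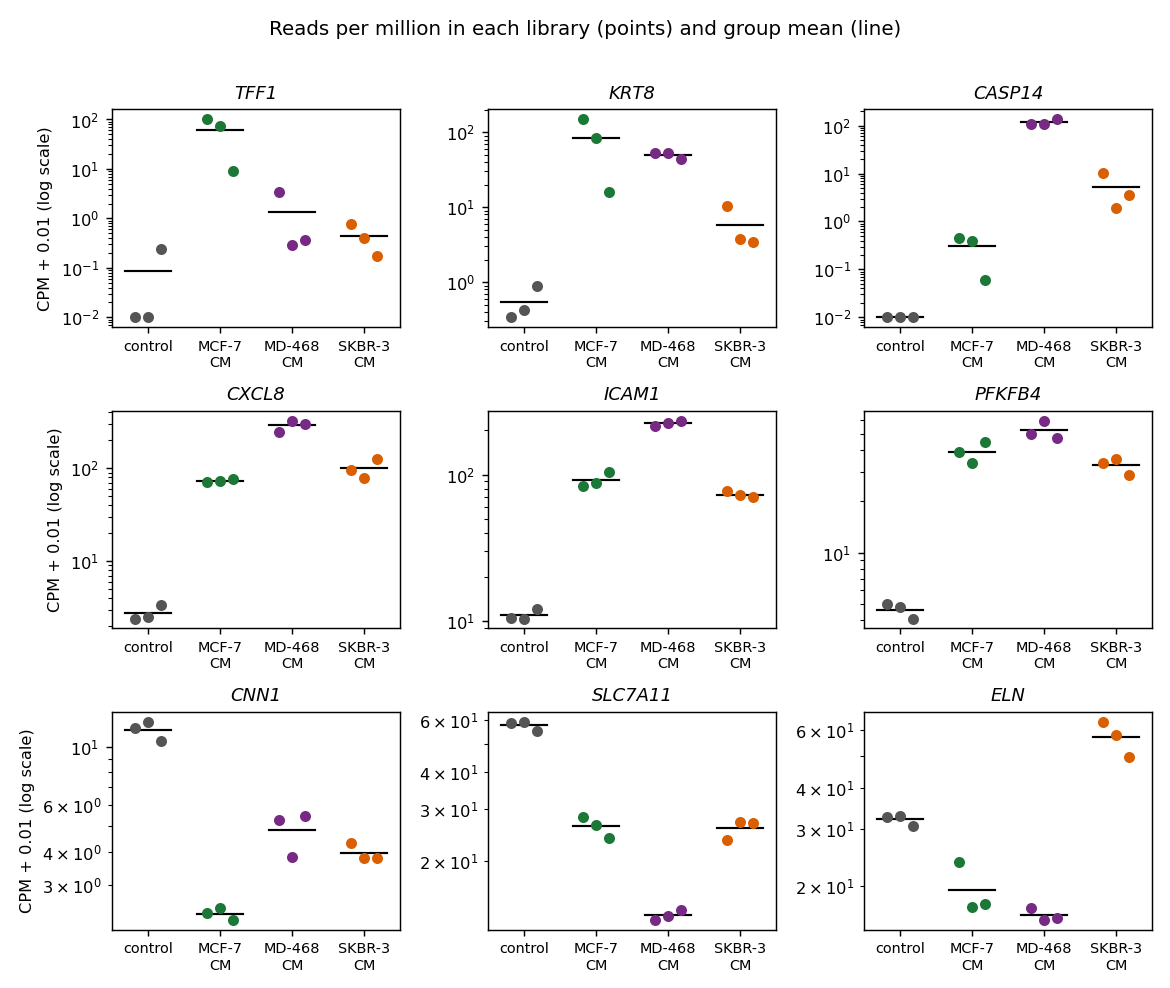
CPM plus 0.01 (log scale) for 9 genes in each of the 12 libraries, points being libraries and lines group means, by group. TFF1 and KRT8 differ widely between the 3 MCF-7 CM libraries, while CXCL8, ICAM1 and PFKFB4 sit close together within each group and above every control.

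Which genes differ between myotubes in MD-468 CM and in vehicle? Inflammatory genes rose most widely here: CCL20, a chemokine for lymphocytes and dendritic cells, and ICAM1, an adhesion receptor for leukocytes, rose with nearly all other NF-kB targets. Interferon-stimulated and glycolytic genes rose as well, and STC1, a secreted glycoprotein of wound and hypoxia responses, rose strongly. Genes for cystine import, cholesterol uptake and growth inhibition fell: SLC7A11, LDLR and MSTN. The MD-468 line markers KRT5 and KRT6B were present in these libraries and almost absent from controls, as were the cornified-layer protease CASP14, the serine proteases KLK5 and KLK6, and the keratin KRT4.

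With MD-468 CM 3456 genes (24.3%) passed in edgeR, 1856 higher and 1600 lower (1510 and 1538 among genes at 1 CPM or more in controls), and 706 changed over 2-fold, 549 higher and 157 lower. Of those rises, 347 of the 549 had a control mean under 1 CPM. CASP14 had no control read and 118 CPM in MD-468 CM, at least 4802-fold. AZGP1, a secreted lipid-mobilising glycoprotein, rose at least 780-fold (18.9 CPM) and the gap junction protein GJB3 at least 228-fold (5.44 CPM), both from 0 control reads. KLK5 had 1 control read, giving a ratio of 1591 with a 95% counting interval of 285 to 62905. On the same footing were KLK6 (1151, 206 to 45517), KRT4 (929.8, 166 to 36774) and the membrane protease ST14 (691, 123 to 27330). KRT6B had 2 control reads (502, 139 to 4154).

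The largest fall in MD-468 CM was that of SLC7A11, from 57.7 to 13.1 CPM (−2.14 ± 0.09, edgeR adjusted p = 1.5e-09), ahead of COMP (−1.76 ± 0.20), ALPK2 (−1.75 ± 0.07) and RELN (−1.72 ± 0.20). MARCH4, a ubiquitin ligase of membrane proteins (−1.72), and MRVI1, a calcium-release regulator of smooth muscle (−1.67), fell alongside. MSTN went from 52.2 to 16.3 CPM (−1.68 ± 0.12, edgeR adjusted p = 2.7e-07) and LDLR from 65.2 to 21.1 CPM (−1.62 ± 0.10, edgeR adjusted p = 4.8e-08).

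NF-kB targets rose in 33 of 37 cases in MD-468 CM, with 2 lower and 2 not passing (33 and 2 adjusted over the list alone, limma camera adjusted p = 1.3e-25, adjusted p = 0.048 with an estimated correlation). ICAM1 went from 11 to 225 CPM (4.36 ± 0.10), SOD2 from 303 to 1935 CPM (2.67 ± 0.08), CXCL1 from 0.201 to 41.2 CPM, and CCL20 rose by 5.28 ± 0.19. CXCL8 reached 243, 327 and 298 CPM in the 3 libraries (6.71). Of 39 interferon-stimulated genes 32 rose, 2 fell and 5 did not pass (36 and 2 adjusted over the list alone, limma camera adjusted p = 3.3e-13, adjusted p = 0.27 with an estimated correlation). They include IFIT3 (1.75, 16.6 to 55.7 CPM), the RNA sensor IFIH1 (1.53) and PARP14 (1.17). Glycolysis and hypoxia genes rose in 29 of 34 cases, with 0 lower and 5 not passing (30 and 0 adjusted over the list alone, limma camera adjusted p = 2.7e-22, adjusted p = 0.048 with an estimated correlation). PFKFB4 (3.50, 52.3 CPM), HILPDA (2.88, 49.7 CPM), NDRG1 (1.87) and BNIP3 (1.59) are among them. All 18 epithelial markers rose in the same libraries, for example KRT7 (5.13 ± 0.30, 0.821 to 29.1 CPM). The MD-468 line marker KRT5 rose there too (6.34 ± 0.33, 0.362 to 30.1 CPM).

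ATF4 and amino acid genes fell in 17 of 30 cases in MD-468 CM, 3 rose and 10 did not pass (3 and 18 adjusted over the list alone, limma camera adjusted p = 9.0e-06, adjusted p = 0.086 with an estimated correlation). SLC7A11 led, PSAT1 went from 103 to 50.6 CPM (−1.02), and against the list DDIT4 rose by 1.59 and the lipoprotein receptor VLDLR by 1.15. TGF-beta response genes were lower in 14 of 27 cases and higher in 2, with 11 not passing (2 and 14 adjusted over the list alone, limma camera adjusted p = 2.5e-04, adjusted p = 0.28 with an estimated correlation). COMP, ACTA2 (−0.74, 593 CPM) and the matrix glycoprotein THBS1 (−0.75) were among those lower, beside 4 of 9 smooth muscle markers (limma camera adjusted p = 0.018, adjusted p = 0.21 with an estimated correlation). Extracellular matrix genes were lower in 12 of 38 cases and higher in 5, with 21 not passing (5 and 14 adjusted over the list alone, limma camera adjusted p = 0.047, adjusted p = 0.82 with an estimated correlation). The proteoglycan VCAN fell (−0.98), while the collagen hydroxylases P4HA1 (1.01) and PLOD2 (1.08) rose. This list no longer passed without control 1 or 2 (limma camera adjusted p = 0.070 and 0.065), MCF-7 CM 1 or 3 (0.051 and 0.054), MD-468 CM 2 or 3 (0.088 and 0.079) or SKBR-3 CM 1 (0.052), nor with the trend with gene length removed (0.37).

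Wound healing and matrix proteolysis genes rose in 13 of 27 cases in MD-468 CM, with 2 lower and 12 not passing (limma camera adjusted p = 0.011, adjusted p = 0.28 with an estimated correlation). STC1 rose by 2.90 ± 0.11, the growth factor EREG by 0.96 and the matrix protein TNC by 0.67. Cholesterol and SREBP targets were lower in 9 of 32 cases, with 0 higher (1 and 10 adjusted over the list alone, limma camera adjusted p = 0.026, adjusted p = 0.48 with an estimated correlation). INSIG1 stood at −1.33. Without MD-468 CM 3 this list had a limma camera adjusted p = 0.063. Fatty acid oxidation and PPAR targets rose in 5 of 21 cases (0 lower, limma camera adjusted p = 0.011, adjusted p = 0.30 with an estimated correlation), led by ANGPTL4, a lipoprotein lipase inhibitor (2.20), and PLIN2 (1.92, 273 CPM). With them 2 of 8 adipocyte markers were higher (limma camera adjusted p = 0.043, adjusted p = 0.21 with an estimated correlation, 0.068 with the length trend removed). Autophagy genes rose in 7 of 38 cases (0 lower, limma camera adjusted p = 0.011, adjusted p = 0.31 with an estimated correlation), among them the mitophagy receptors BNIP3L (0.97) and OPTN (0.55).

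Small upward shifts took in 3 lists of short, highly expressed genes in MD-468 CM. Ribosomal protein genes rose in 13 of 47 cases (19 and 0 adjusted over the list alone, limma camera adjusted p = 1.9e-06, adjusted p = 0.65 with an estimated correlation), RPS8 by 0.34 (edgeR adjusted p = 0.055 without control 2). Oxidative phosphorylation genes rose in 10 of 42 cases (0 lower, limma camera adjusted p = 6.0e-04, adjusted p = 0.73 with an estimated correlation), such as COX4I1 of complex IV (0.28). Proteasome genes did in 5 of 30 (0 lower, limma camera adjusted p = 0.0059, adjusted p = 0.73 with an estimated correlation), such as PSMA3 (0.42). Across genes, the change in MD-468 CM falls with gene length (Spearman −0.330), and removing that trend ended these 3 list calls (limma camera adjusted p = 0.080, 0.22 and 0.25).

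Muscle lists were not called in MD-468 CM: sarcomere genes (3 of 48 higher, 6 lower, limma camera adjusted p = 0.80), myogenic regulators (4 of 22 higher, 3 lower, limma camera adjusted p = 0.83) and atrophy genes (6 of 29 higher, 3 lower, limma camera adjusted p = 0.63, 0.021 with fry). Single genes did pass. The giant sarcomere spring TTN (−0.68) and the myoblast determination factor MYF5 (−0.67) fell. FBXO32 rose from 137 to 169.5 CPM (0.31 ± 0.07, edgeR adjusted p = 0.0043) and the differentiation factor MYOG by 0.42 (edgeR adjusted p = 0.039). The MYOG call was lost with a replicate block, without control 1, 2 or 3 (edgeR adjusted p = 0.14, 0.078 and 0.083) and without MD-468 CM 1 or 2 (0.14 and 0.11). IL6 went from 9.46 to 52.5 CPM (2.47), and the growth factor receptor EGFR, 1 of the 12 MD-468 line markers, from 70.0 to 150.6 CPM (1.11 ± 0.07).

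Which genes differ between myotubes in SKBR-3 CM and in vehicle? The neutrophil chemokines CXCL1, CXCL6 and CXCL8 and the granulocyte growth factor CSF3 rose, as did the glycolysis regulator PFKFB4. Amino acid genes under ATF4 fell here too, from the importer SLC7A11 to the glutathione-degrading CHAC1. ELN, the elastin of elastic fibres, rose. Few epithelial transcripts passed in these libraries, CASP14 and KRT8 among them.

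SKBR-3 CM changed 2421 genes (17%) in edgeR, 1255 upward and 1166 downward, with 276 over 2-fold, 203 higher and 73 lower. Among the rises, 120 of the 203 had a control mean under 1 CPM. Without control 1, 2 or 3 the count was 1508, 1294 (646 higher, 648 lower) or 1485. CASP14 had 0 control reads and 10.4, 1.85 and 3.50 CPM in the 3 SKBR-3 CM libraries. In the same libraries the MD-468 line markers stood at a median of 8.74, 1.41 and 1.26% of their excess in MD-468 CM. CXCL1 rose by 5.91 ± 0.31 (0.201 to 13.2 CPM), CXCL8 by 5.17 ± 0.20 (2.74 to 99.9 CPM, edgeR adjusted p = 2.0e-09). CXCL6 rose by 4.57 ± 0.22, CSF3 by 3.37 ± 0.23, CCL20 by 3.23 ± 0.20 and PFKFB4 by 2.82 ± 0.14. KRT8 rose by 3.37 ± 0.87 (edgeR adjusted p = 0.018), but did not pass without control 1 (edgeR adjusted p = 0.066), control 2 (edgeR adjusted p = 0.068) or SKBR-3 CM 1 (edgeR adjusted p = 0.071). The largest falls were those of RELN (−2.02 ± 0.21), CHAC1 (−1.73), CNN1 (−1.54 ± 0.14), MRVI1 (−1.53), PCK2 (−1.47), the muscle Z-disc protein IGFN1 (−1.41), LDLR (−1.34 ± 0.10) and the muscle lectin CHODL (−1.32).

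NF-kB targets rose in 22 of 37 cases in SKBR-3 CM, with 2 lower and 13 not passing (26 and 2 adjusted over the list alone, limma camera adjusted p = 1.2e-15, adjusted p = 0.048 with an estimated correlation). SOD2 rose to 1271 CPM (2.07 ± 0.07, edgeR adjusted p = 1.3e-09) and ICAM1 to 72.9 CPM (2.73 ± 0.10). Interferon-stimulated genes rose in 16 of 39 cases, 1 fell and 22 did not pass (17 and 2 adjusted over the list alone, limma camera adjusted p = 8.9e-06, adjusted p = 0.55 with an estimated correlation). PARP14 stood at 0.73 ± 0.08 and IFIT3 at 0.96 ± 0.17. Glycolysis and hypoxia genes rose in 25 of 34 cases, with 0 lower and 9 not passing (26 and 0 adjusted over the list alone, limma camera adjusted p = 1.5e-17, adjusted p = 0.056 with an estimated correlation). HILPDA rose by 2.38, BNIP3 by 1.33 ± 0.07 and NDRG1 by 1.31 ± 0.08. Epithelial markers rose in 3 of 18 cases in these libraries (8 adjusted over the list alone, limma camera adjusted p = 2.2e-04, adjusted p = 0.52 with an estimated correlation).

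ATF4 and amino acid genes fell in 23 of 30 cases in SKBR-3 CM, 4 rose and 3 did not pass (4 and 23 adjusted over the list alone, limma camera adjusted p = 2.1e-10, adjusted p = 0.048 with an estimated correlation). SLC7A11 (−1.16), PSAT1 (−0.96 ± 0.07), MTHFD2 (−0.98) and SLC7A1 (−0.98) were lower. Cholesterol and SREBP targets were lower in 7 of 32 cases and higher in 1 (1 and 9 adjusted over the list alone, limma camera adjusted p = 6.0e-04, adjusted p = 0.26 with an estimated correlation), with INSIG1 at −0.74. Fatty acid oxidation and PPAR targets rose in 10 of 21 cases and fell in 1 (11 and 2 adjusted over the list alone, limma camera adjusted p = 0.0014, adjusted p = 0.19 with an estimated correlation). PLIN2 rose by 1.43 ± 0.08, ANGPTL4 by 1.02 and FABP3 by 0.64. Beside this list, 3 of 8 adipocyte markers were higher (limma camera adjusted p = 0.019, adjusted p = 0.21 with an estimated correlation). MAPK immediate early and feedback genes were lower in 11 of 27 cases and higher in 3 (4 and 13 adjusted over the list alone, limma camera adjusted p = 0.012, adjusted p = 0.27 with an estimated correlation). The ERK inhibitors SPRY4 (−0.66) and DUSP5 (−0.61) fell.

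TGF-beta response genes were not called as a list in SKBR-3 CM, with 8 of 27 higher and 11 lower (limma camera adjusted p = 0.40, 0.036 with fry); ACTA2 (−0.71 ± 0.07) and CYR61 (−0.88) fell while ELN rose (0.84 ± 0.12). Short, abundant genes shifted upward, first the ribosomal proteins (17 of 47 higher, 0 lower, 32 and 0 adjusted over the list alone, limma camera adjusted p = 3.5e-08, adjusted p = 0.55 with an estimated correlation). Proteasome genes (5 of 30 higher, 0 lower, 7 and 0 adjusted over the list alone, limma camera adjusted p = 2.9e-04, adjusted p = 0.68 with an estimated correlation) and oxidative phosphorylation (8 of 42 higher, 0 lower, 9 and 0 adjusted over the list alone, limma camera adjusted p = 0.0024, adjusted p = 0.77 with an estimated correlation) followed. COX4I1 rose by 0.30 ± 0.07 and PSMB2 by 0.26. Removing the trend with gene length (Spearman −0.264) ended the oxidative phosphorylation call (limma camera adjusted p = 0.38, median change 0.13 before and 0.07 after). The ribosomal and proteasome lists still passed (0.0086 and 0.018). Autophagy genes rose in 6 of 38 cases (0 lower, limma camera adjusted p = 0.029, adjusted p = 0.41 with an estimated correlation), BNIP3L by 0.92. Without control 1 the autophagy and oxidative phosphorylation lists no longer passed (limma camera adjusted p = 0.089 and 0.069), and neither did autophagy without SKBR-3 CM 2 (limma camera adjusted p = 0.065).

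In the muscle lists SKBR-3 CM brought no call: sarcomere genes (8 of 48 higher, 5 lower, limma camera adjusted p = 0.85), myogenic regulators (7 of 22 higher, 4 lower, limma camera adjusted p = 0.52) and atrophy genes (4 of 29 higher, 5 lower, limma camera adjusted p = 0.80). MYOD1 (0.61, edgeR adjusted p = 0.011) and MYMX (1.18 ± 0.08) rose, as did MYOG (0.43, edgeR adjusted p = 0.047), while TTN (−0.66) and MSTN (−0.84) fell. MYOG no longer passed with a replicate block, without control 1, 2 or 3 (edgeR adjusted p = 0.15, 0.096 and 0.098) or without SKBR-3 CM 1 or 2 (0.13 and 0.11). TTN no longer passed without control 1 or 2 (edgeR adjusted p = 0.051 and 0.062) or SKBR-3 CM 3 (0.057). The chemokine receptor CXCR4, which guides muscle progenitors, rose by 2.87 ± 0.26, PDK4 by 1.57 and IL6 by 1.42 (25.35 CPM). In none of the 3 media did TRIM63, the fusion protein MYMK, the myosins MYH3, MYH8, MYH2 and MYH7, skeletal actin ACTA1, creatine kinase CKM, the glucocorticoid target FKBP5 or the ankyrin ANK1 pass in edgeR. Lists without a call against control in any medium were also calcium handling, satellite cell, glucocorticoid, STAT3, Notch, insulin and IGF, unfolded protein, NRF2, p53, cell cycle, splicing and heat shock genes. Their limma camera adjusted p ran from 0.054 (STAT3 genes in MD-468 CM, 5 of 18 higher) to 0.98 (cell cycle genes in MD-468 CM, 2 of 40 higher and 1 lower). The STAT3 list in MD-468 CM passed without control 2, MD-468 CM 3 or SKBR-3 CM 3 (limma camera adjusted p = 0.047, 0.027 and 0.045), and the NRF2 list in SKBR-3 CM without control 3 (0.031). Against no change, in fry, the STAT3 list had 0.027.

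**Figure D2:**
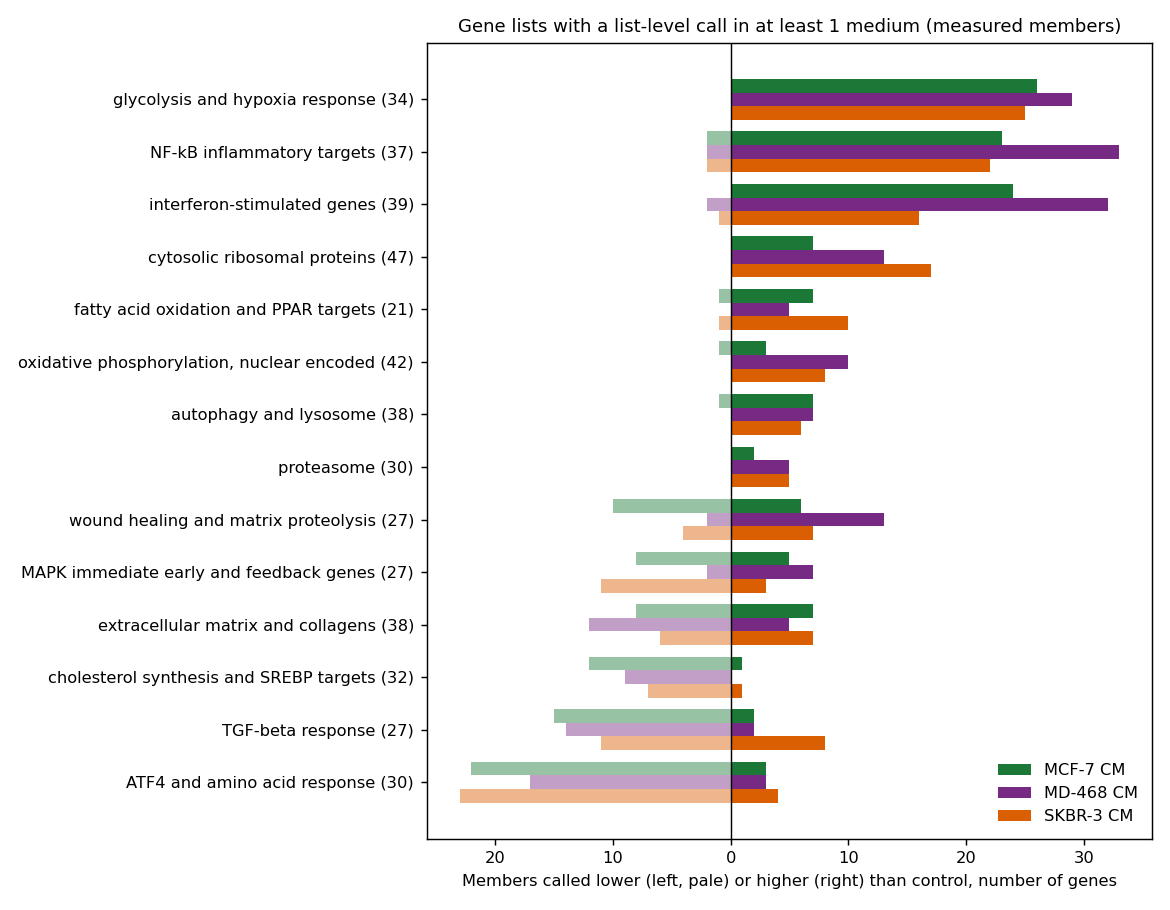
Number of measured members of each gene list called higher (right) or lower (left, pale) than control, for each conditioned medium; numbers after list names are measured members. Most called members of the glycolysis, NF-kB and interferon lists lie to the right and most of the ATF4 list to the left in all 3 media; TGF-beta response genes have 8 to the right and 11 to the left in SKBR-3 CM.

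What changes on the mean of the 3 media against vehicle? Inflammatory chemokines and adhesion genes rose with glycolytic genes, while amino acid and sterol genes fell, as they did in each medium. The mean passed in 4134 genes (edgeR), 2137 higher and 1997 lower. Without control 1, 2 or 3 the count was 2733, 2337 or 2643. More genes were lower than higher without MCF-7 CM 2 (2052 higher, 2160 lower), with MCF-7 CM by library 3 alone (1807 and 1878), with 2 libraries per group (2225 and 2288) and among genes at 1 CPM or more in controls (1883 and 1937). CXCL1 rose by 6.54 ± 0.28, KRT8 by 5.68, CXCL8 by 5.54 ± 0.19, CSF3 by 4.08, CCL20 by 4.07 and ICAM1 by 3.38 ± 0.09 (edgeR adjusted p = 5.2e-11). RELN (−2.01 ± 0.15), CNN1 (−1.70), CHAC1 (−1.59), ALPK2 (−1.51 ± 0.05), SLC7A11 (−1.48) and the cornified-envelope protein KPRP (−1.42) fell most.

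By list, on the mean of the media, NF-kB targets rose in 27 of 37 cases and fell in 2 (30 and 2 adjusted over the list alone, limma camera adjusted p = 1.0e-18, adjusted p = 0.048 with an estimated correlation). So did glycolysis genes in 28 of 34 (29 and 0 adjusted over the list alone, limma camera adjusted p = 8.1e-20, adjusted p = 0.048 with an estimated correlation) and interferon-stimulated genes in 27 of 39, 2 being lower (29 and 2 adjusted over the list alone, limma camera adjusted p = 4.7e-10, adjusted p = 0.35 with an estimated correlation). ATF4 genes fell in 23 of 30 cases and rose in 4 (limma camera adjusted p = 2.0e-08, adjusted p = 0.048 with an estimated correlation). TGF-beta response genes, not called in SKBR-3 CM, fell in 14 of 27 and rose in 5 (6 and 14 adjusted over the list alone, limma camera adjusted p = 0.0015, adjusted p = 0.36 with an estimated correlation), and cholesterol genes fell in 12 of 32 and rose in 2 (2 and 14 adjusted over the list alone, limma camera adjusted p = 0.0018, adjusted p = 0.29 with an estimated correlation). Fatty acid oxidation (11 of 21 higher, limma camera adjusted p = 0.0046, adjusted p = 0.27 with an estimated correlation) and ribosomal genes (22 of 47 higher, 28 adjusted over the list alone, limma camera adjusted p = 6.3e-06, adjusted p = 0.68 with an estimated correlation) also shifted upward, PLIN2 and RPS8 being members.

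Against vehicle, 1284 genes changed in the same direction in all 3 media, where independent calls would give 38.2. Leaving out control 1, 2 or 3, the count was 845, 747 or 820. MCF-7 CM and MD-468 CM had 1914 genes in the same direction (445 if independent, 1230 without control 2). MCF-7 CM and SKBR-3 CM had 1762 (311 if independent, 983 without control 2 and 1057 without control 3), and MD-468 CM with SKBR-3 CM 1609 (295 if independent, 972, 884 and 1055 without control 1, 2 and 3). Simulated media without any effect, sharing the same controls, gave 0 such genes, which is chance with no effect and does not measure what the controls add to real effects. All comparisons use the same 3 controls, which are too few to split between the media. The excess over independent calls may hold what the media share, what these controls bring to each comparison, and carcinoma transcripts. Among genes at 1 CPM or more in controls, 1233 genes changed in the same direction in all 3 media. The covariance of the log2 changes was 0.245, 0.182 and 0.209 in these pairs, against 0.0119, 0.0118 and 0.0119 in the simulation. Correlations were 0.72, 0.80 and 0.81 against a simulated 0.49. Above the simulation the covariance was 0.233, 0.170 and 0.197. The covariances and correlations include carcinoma transcripts, some with large changes, and were not computed without them. SOD2, ICAM1, PFKFB4 and HILPDA are among the genes higher in all 3 media, and CNN1, RELN, PSAT1 and SLC7A11 among those lower.

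How does MD-468 CM differ from MCF-7 CM? Inflammatory and wound genes were higher in MD-468 CM, as were the keratins KRT6A and KRT6B and the protease inhibitor SLPI. MCF-7 line markers were lower, among them TFF1, the oestrogen-responsive GREB1 and the transcription factors FOXA1 and GATA3. The edgeR test gave 1358 genes, 660 higher and 698 lower in MD-468 CM, and 287 over 2-fold. The count was 772, 779 and 3117 without MCF-7 CM 1, 2 and 3, and 750 and 620 without MD-468 CM 1 and 2. More genes were higher than lower in each of these fits (435 and 337, 409 and 370, 1685 and 1432, 388 and 362, 341 and 279). The same held with a replicate block (497 and 454), only the groups compared (353 and 283) and MCF-7 CM by library 3 alone (317 and 138). It held too with 2 libraries per group (1401 and 1271) and the length trend removed (654 and 579). More genes were lower without MD-468 CM 3 (918 higher, 974 lower), with RLE scaling (657 and 710) and with DESeq2 (956 and 1019). The same went for no filter (660 and 698) and for genes at 1 CPM or more in controls (513 and 649). KRT6B stood at 7.96 CPM against 0, KRT4 at 7.44 against 0 and SLPI at 7.41 against 0; TFF1 differed by −5.41 ± 0.86 (edgeR adjusted p = 0.0011), SPTSSB by −5.28, GREB1 by −4.09, FOXA1 by −3.70 and GATA3 by −3.60.

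Between these media NF-kB targets were higher with MD-468 CM in 26 of 37 cases and lower in 0 (30 and 0 adjusted over the list alone, limma camera adjusted p = 1.2e-17, adjusted p = 0.048 with an estimated correlation), with ICAM1 at 225 against 92.0 CPM. Wound healing genes were higher in 13 of 27 cases and lower in 2 (14 and 3 adjusted over the list alone, limma camera adjusted p = 2.3e-05, adjusted p = 0.063 with an estimated correlation). Higher too were glycolysis genes (6 of 34, 13 adjusted over the list alone, limma camera adjusted p = 0.0028, adjusted p = 0.59 with an estimated correlation) and interferon-stimulated genes (4 of 39, limma camera adjusted p = 0.0023, adjusted p = 0.73 with an estimated correlation, 0.076 without MCF-7 CM 1). Unfolded protein response genes were higher as well (8 of 22, 11 adjusted over the list alone, limma camera adjusted p = 0.0013, adjusted p = 0.41 with an estimated correlation). Against control, members of this list had fallen in MCF-7 CM, without a list call. Lower were myogenic regulators (6 of 22, 10 adjusted over the list alone, limma camera adjusted p = 0.017, adjusted p = 0.43 with an estimated correlation, 0.14 without MCF-7 CM 3 and 0.11 without MD-468 CM 3). Matrix genes (6 of 38, 7 adjusted over the list alone, limma camera adjusted p = 0.012, adjusted p = 0.76 with an estimated correlation, 0.11 without MCF-7 CM 3) and splicing factors (4 of 42, 6 adjusted over the list alone, limma camera adjusted p = 0.025, adjusted p = 0.76 with an estimated correlation, 0.093 without MCF-7 CM 2, 0.063 without MD-468 CM 1, 0.073 without MD-468 CM 2) were lower as well. The oxidative phosphorylation and ribosomal lists shifted upward with 0 members passing (limma camera adjusted p = 1.5e-04 and 0.0038, adjusted p = 0.73 and 0.77 with an estimated correlation). Across genes this contrast tracks gene length (Spearman −0.372) and GC content (0.437), and with the length trend removed neither list passed (limma camera adjusted p = 0.14 and 0.83), nor did the matrix and splicing lists (0.30 and 0.13). In the same comparison 11 of 12 MD-468 line markers were higher (limma camera adjusted p = 7.4e-18, adjusted p = 0.17 with an estimated correlation) and 7 of 10 MCF-7 line markers lower (limma camera adjusted p = 3.2e-04, adjusted p = 0.42 with an estimated correlation).

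How does SKBR-3 CM differ from MCF-7 CM? The elastin ELN, the matrix protein COMP and CILP, a cartilage protein that binds TGF-beta, were higher in SKBR-3 CM, while TFF1 and BMP7 were lower. The test gave 315 genes in edgeR, 111 higher and 204 lower. This balance turned with MCF-7 CM by library 3 alone (32 higher, 9 lower), with only the groups compared (15 and 3) and with 2 libraries per group (121 and 97). It also turned without MCF-7 CM 1 (65 and 63) and without SKBR-3 CM 1, 2 or 3 (45 and 39, 52 and 49, 86 and 71). Another split of the same 6 libraries gave 1659 genes. Omitting a single library moved the count past 1.5 times each time: 128, 125 and 807 without MCF-7 CM 1, 2 and 3, and 84, 101 and 157 without SKBR-3 CM 1, 2 and 3. CILP differed by 2.02 ± 0.17 (4.10 against 16.7 CPM, edgeR adjusted p = 7.4e-05), COMP by 1.70 ± 0.19 (5.96 against 19.4 CPM), ELN by 1.55 ± 0.12 (19.5 against 57.1 CPM) and the matrix protease ADAMTS16 by 1.37. COMP stood at 18.7 CPM in control, so its difference is a fall in MCF-7 CM, and the extracellular matrix list had no call (0 of 38 passing, limma camera adjusted p = 0.83). SPTSSB (−7.43), TFF1 (−7.12), BMP7 (−4.88, edgeR adjusted p = 0.054 without SKBR-3 CM 2), FOXA1 (−4.52) and MAL2 (−4.27) were lower.

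TGF-beta response genes were higher with SKBR-3 CM than with MCF-7 CM in 10 of 27 cases and lower in 0 (14 and 0 adjusted over the list alone, limma camera adjusted p = 3.1e-12, adjusted p = 0.048 with an estimated correlation). Lower were glycolysis genes (6 of 34, 8 adjusted over the list alone, limma camera adjusted p = 0.0031, adjusted p = 0.59 with an estimated correlation, 0.36 without MCF-7 CM 3). Interferon-stimulated genes were lower as a list (1 of 39, limma camera adjusted p = 0.0034, adjusted p = 0.73 with an estimated correlation, 0.081, 0.053 and 0.14 without MCF-7 CM 2, MCF-7 CM 3 and SKBR-3 CM 1). With 0 members passing, the ribosomal, oxidative phosphorylation and proteasome lists shifted upward (limma camera adjusted p = 9.3e-06, 8.5e-05 and 0.0011, adjusted p = 0.70, 0.73 and 0.73 with an estimated correlation) and the sarcomere list downward (0.037, 0.73 with an estimated correlation). Without SKBR-3 CM 3 the ribosomal, proteasome and sarcomere lists did not pass (limma camera adjusted p = 0.072, 0.21 and 0.074), nor did the sarcomere list without MCF-7 CM 2 or 3 (0.37 and 0.15), MD-468 CM 3 (0.053) or SKBR-3 CM 2 (0.068). Changes in this contrast track gene length (Spearman −0.398) and GC content (0.273). With the length trend removed the ribosomal, oxidative phosphorylation and proteasome lists did not pass (limma camera adjusted p = 0.179, 0.183 and 0.186). Unfolded protein response genes shifted upward with 1 of 22 passing (limma camera adjusted p = 0.0043, adjusted p = 0.48 with an estimated correlation, 0.13 without MCF-7 CM 3). Epithelial markers were lower in 12 of 18 cases (limma camera adjusted p = 5.7e-12, adjusted p = 0.29 with an estimated correlation) and MCF-7 line markers in 9 of 10 (limma camera adjusted p = 1.5e-10, adjusted p = 0.21 with an estimated correlation), beside the glycolysis and interferon lists.

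How does SKBR-3 CM differ from MD-468 CM? Inflammatory, interferon, glycolytic and MAPK genes were lower in SKBR-3 CM, as were KRT4, KRT6A and DSG2, a desmosomal cadherin. ELN, CILP and the joint lubricant PRG4 were higher. There were 1295 genes in edgeR, 480 higher and 815 lower, 803 without MD-468 CM 2. Changes in this contrast track GC content (Spearman −0.325), a trend that was not removed, and gene length more weakly (0.126). CILP differed by 2.00, COMP by 1.81 (5.53 against 19.4 CPM, 18.7 in control), ELN by 1.81 ± 0.12 (16.3 against 57.1 CPM, edgeR adjusted p = 1.1e-06), PRG4 by 1.65 (5.17 against 16.0 CPM) and BRINP1, a neural cell cycle inhibitor, by 1.63 ± 0.11. KRT4 (−5.64), SLPI (−5.30), DSG2 (−5.12), KRT6A (−4.97) and KRT6B (−4.95) were lower.

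Here NF-kB targets were lower with SKBR-3 CM in 26 of 37 cases and higher in 1 (1 and 31 adjusted over the list alone, limma camera adjusted p = 2.7e-22, adjusted p = 0.048 with an estimated correlation), with ICAM1 at 72.9 against 225 CPM. Interferon-stimulated genes were lower in 11 of 39 (22 adjusted over the list alone, limma camera adjusted p = 2.2e-09, adjusted p = 0.36 with an estimated correlation) and glycolysis genes in 13 of 34 (17 adjusted over the list alone, limma camera adjusted p = 1.8e-09, adjusted p = 0.19 with an estimated correlation). MAPK genes were lower in 11 of 27 (limma camera adjusted p = 0.0014, adjusted p = 0.15 with an estimated correlation) and wound healing genes in 10 of 27, with 1 higher (limma camera adjusted p = 9.8e-04, adjusted p = 0.16 with an estimated correlation). TGF-beta response genes were higher in 8 of 27 cases and lower in 1 (9 and 3 adjusted over the list alone, limma camera adjusted p = 0.0018, adjusted p = 0.36 with an estimated correlation). Matrix genes were higher in 3 of 38 (limma camera adjusted p = 0.012, adjusted p = 0.76 with an estimated correlation, 0.062 without SKBR-3 CM 1 and 0.29 without SKBR-3 CM 2). STAT3 response genes were lower in 4 of 18 (limma camera adjusted p = 0.010, adjusted p = 0.57 with an estimated correlation, 0.12 without SKBR-3 CM 3). Of the MD-468 line markers, 12 of 12 were lower (limma camera adjusted p = 3.5e-20, adjusted p = 0.17 with an estimated correlation), together with 15 of 18 epithelial markers (limma camera adjusted p = 2.6e-13, adjusted p = 0.28 with an estimated correlation).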

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

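The contrasts between media were planned; looking through them for genes that changed in opposite directions against control was chosen only after these results were seen. In MD-468 CM and MCF-7 CM, 40 genes changed in opposite directions with the difference itself passing in edgeR, and 6 of them are members of the gene lists. IGFBP3, which binds insulin-like growth factors, rose in MD-468 CM (0.41) and fell in MCF-7 CM (−0.35); so did the plasminogen activator PLAT (0.22 and −0.47), the urokinase receptor PLAUR (0.41 and −0.53), the heparan sulphate proteoglycan SDC4 (0.27 and −0.56) and the growth factor TGFA (0.46 and −0.48). ID2, which blocks bHLH transcription factors, went the other way (−0.39 and 0.29).

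Between SKBR-3 CM and MCF-7 CM 9 genes did so, 1 of them in the lists: ELN rose in SKBR-3 CM (0.84 ± 0.12) and fell in MCF-7 CM (−0.71 ± 0.12; difference 1.55, edgeR adjusted p = 7.4e-05). Between SKBR-3 CM and MD-468 CM 52 genes did, 8 of them in the lists. ELN (0.84 and −0.97), the muscle growth factor IGF1 (0.71 ± 0.22 and −1.64 ± 0.27) and ID2 (0.26 and −0.39) rose in SKBR-3 CM and fell in MD-468 CM. FOSL1, a subunit of the AP-1 transcription factor (−0.40 and 0.36), the metallothionein MT1X (−0.60 and 0.62), the secreted pattern receptor PTX3 (−0.31 and 0.66), SDC4 (−0.56 and 0.27) and the signalling inhibitor SPRY1 (−0.57 and 0.43) went the opposite way.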

How the results depend on the processing

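The settings with MCF-7 CM by its library 3 alone, 2 libraries per group, genes at 1 CPM or more in controls and length removal were chosen only after the results were seen; the others were planned. Libraries left out singly gave 2238 to 4620 genes for MCF-7 CM, 2420 to 3111 for MD-468 CM, 1294 to 2152 for SKBR-3 CM, 2337 to 4639 for their mean, 620 to 3117 for MD-468 against MCF-7 CM, 84 to 807 for SKBR-3 against MCF-7 CM and 803 to 1133 for SKBR-3 against MD-468 CM. Overlaps ran from 747 to 845 for all 3 media, 1230 to 1368 for MCF-7 and MD-468 CM, 983 to 1180 for MCF-7 and SKBR-3 CM and 884 to 1055 for MD-468 and SKBR-3 CM, where every fit had fewer controls; list calls ran from 59 to 72 of 203 and marker list calls from 22 to 30 of 70. MCF-7 CM by its library 3 alone, assumed to vary like the other groups, gave 1217 genes (691 higher, 526 lower) against control, 455 (317 and 138; 69.7% higher, against 48.6%) for MD-468 against MCF-7 CM and 41 (32 and 9; 78.0% higher, against 35.2%) for SKBR-3 against MCF-7 CM. With 2 libraries per group MD-468 against MCF-7 CM gave 2672 genes (1401 and 1271); SKBR-3 against MCF-7 CM gave 218 (121 and 97; 55.5% higher). A fit of only the groups compared gave 636 (353 and 283) and 18 (15 and 3) for these contrasts, genes at 1 CPM or more in controls 203 (88 and 115) and DESeq2 641 (228 and 413) for SKBR-3 against MCF-7 CM. Estimated correlations left 10 of 69 gene list calls and 0 of 27 marker list calls (fry 71 and 37). Among genes at 1 CPM or more in controls, the MD-468 line markers in SKBR-3 CM changed direction (limma camera adjusted p = 0.71), and the epithelial markers there had 0.54. RLE scaling changed no list call and shifted all genes by a median of at most 0.0088; of 544 results for named genes, 463 called, DESeq2 ended 1 call and added 13, and length removal ended 35 and added 6. Over all fits with a library left out, 3114 gene results did not change, 209 calls ended and 13 were added. The replicate numbers do not pair the samples: 7 of 18 same-numbered pairs correlate above 0.1 (from −0.40 to 0.38, other pairs up to 0.44) and 3 of 12 samples correlate best with their own number. The replicate block gave 197 genes (73 and 124) for SKBR-3 against MCF-7 CM, kept every gene list call, added 1 marker list call and ended 17 calls of named genes. Why these settings move the counts was not tested.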

Other observations

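The tests of carcinoma RNA and of gene length in this part were chosen only after the results they weigh were seen; the splits of the samples were planned. Adipocyte markers shifted upward in MCF-7, MD-468 and SKBR-3 CM, with 3, 2 and 3 of 8 higher (limma camera adjusted p = 0.046, 0.043 and 0.019; adjusted p = 0.21 in each with an estimated correlation). The fat regulator PPARG went from 7.46 to 12.3 and 13.8 CPM in MCF-7 and MD-468 CM (0.72 ± 0.09 and 0.89 ± 0.09) and the hormone LEP from 1.40 to 4.67 CPM in MCF-7 CM (1.73 ± 0.27). The adipocyte call in MCF-7 CM ended without control 3, MCF-7 CM 2 or 3, MD-468 CM 1 or 2, or SKBR-3 CM 1, 2 or 3 (limma camera adjusted p = 0.052, 0.057, 0.068, 0.052, 0.066, 0.056, 0.051 and 0.062), and in MD-468 CM without control 3, MD-468 CM 1 or SKBR-3 CM 1 or 3 (0.055, 0.059, 0.051 and 0.059). Both ended with the length trend removed (limma camera adjusted p = 0.068 in each). Of the 9 smooth muscle markers, 4 are held by other lists too, CNN1, ACTA2 and TAGLN by the TGF-beta list. Smooth muscle calls in MCF-7 and SKBR-3 CM ended with 2 libraries per group (limma camera adjusted p = 0.13 and 0.099). These markers shifted downward, with 4 of 9 lower in each medium (limma camera adjusted p = 0.019, 0.018 and 0.014; adjusted p = 0.21 in each with an estimated correlation), such as the actin nucleator LMOD1 (44 to 22.6, 19.9 and 22.8 CPM) and the actin-binding TAGLN (1774 to 1095 CPM in MCF-7 CM).

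Single genes passed in lists without a call against control. Of those given here, PDK1 is also in the called glycolysis list and VCAM1 in the called NF-kB list. IRS2, which relays insulin signals, fell in all 3 media (−1.05, −0.88 and −1.14 ± 0.10; 60.4 to 29.2, 32.9 and 27.5 CPM), the Notch effector HEYL fell (−0.43, −0.96 and −0.62), the mitochondrial gatekeeper PDK1 rose (1.46, 1.56 and 1.40 ± 0.09), and the transcriptional repressor BCL6, a STAT3 target, rose in MCF-7 and MD-468 CM (0.55 and 0.44). VCAM1, an adhesion receptor of progenitors, rose by 1.07 in MD-468 CM, the stress sensor ERN1 fell in all 3 (−0.63, −0.57 and −0.57), and the splicing factor SRSF7 fell in MCF-7 CM (−0.70). Fibroblast markers (3, 2 and 4 of 13 higher; 0, 1 and 0 lower), endothelial, immune and neural markers were not called in any medium, except fibroblast markers in SKBR-3 CM without control 3 or SKBR-3 CM 3 (limma camera adjusted p = 0.037 and 0.036, against 0.054) or with the length trend removed (0.043), and fry calls, against no change, for fibroblast markers in all 3 media and for endothelial and immune markers in MD-468 and SKBR-3 CM, and PDGFRA, a fibroblast receptor, rose from 51.4 to 87.3 and 89.3 CPM in MCF-7 and MD-468 CM.

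Transcripts of carcinoma lines are the first pattern weighed. The 31 carcinoma markers under 1 CPM in the controls sum to 454, 290.3 and 46.2 CPM in the MCF-7 CM libraries, 218.5, 229 and 189.9 in MD-468 CM and 41.8, 18.2 and 15.4 in SKBR-3 CM, against 4.73, 5.75 and 6.80 in control. In MCF-7 CM 90% of 20 markers, the abundant KRT8 and TFF1 included, have a ratio of library 3 to library 1 within a factor of 2 of the median (median 0.0829, quartiles 0.0637 to 0.105, range 0.0586 to 0.265), and in SKBR-3 CM 1 100% of 10 MD-468 line markers have an excess, as a share of that in MD-468 CM, within a factor of 2 of the median (median 8.74%, range 5.52 to 13.8%, against medians of 1.41 and 1.26% in the other SKBR-3 CM libraries), as RNA from the lines would give. By list, 17 of 18 epithelial and 9 of 10 MCF-7 line markers rose in MCF-7 CM (limma camera adjusted p = 5.0e-11 and 4.6e-07; adjusted p = 0.30 and 0.29 with an estimated correlation), 18 of 18 epithelial, 12 of 12 MD-468 line and 4 of 10 MCF-7 line markers in MD-468 CM (limma camera adjusted p = 4.6e-13, 2.2e-14 and 0.0055; adjusted p = 0.28, 0.21 and 0.51 with an estimated correlation), and 3 of 10 MCF-7 line and 5 of 12 MD-468 line markers in SKBR-3 CM (limma camera adjusted p = 0.028 and 0.012; adjusted p = 0.61 and 0.51 with an estimated correlation, 0.080 and 0.061 without SKBR-3 CM 1). Carcinoma RNA or cells carried in the medium, or a mix between libraries, may account for this. In SKBR-3 CM 1, RNA from MD-468 cells would have to come from another medium or library, since SKBR-3 cells conditioned that medium. TFF1 reads were 127, 10 and 9 in MD-468 CM 1, 2 and 3, which were not held in MCF-7 CM. An induction in the myotubes that differs in strength between libraries could give a common ratio too. These markers were also picked by a call in the same data. Induction was tested in SKBR-3 CM only. It cannot be told apart there, since 7 of the 10 SKBR-3 line markers (median change −0.011, no list call) are expressed in controls.

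Second is the rise of NF-kB, interferon and glycolysis genes, which carcinoma RNA might bring. The values against that are median ratios, library 3 to library 1, of the excess over control in MCF-7 CM. They are 1.199 for the 23 NF-kB members called higher and 1.14 for the 24 interferon members called higher. The markers, picked by the same call, stand at 0.0829. Such a call, used for the glycolysis members too, favours an even excess, so members that vary as the markers do may be left out. The ratio of library 2 to library 1 is 2.08 for interferon members (quartiles 1.70 to 2.57), above the 0.553 of the markers, so MCF-7 CM 2 stands apart for that list. Against RNA from MD-468 cells stand the members called higher in MD-468 CM. Their median excess in SKBR-3 CM 1, 2 and 3 is 30.8, 27.4 and 33.7% of that in MD-468 CM for NF-kB members. It is 24.0, 46.9 and 56% for interferon members and 61.0, 69.0 and 50.6% for glycolysis members. The markers stand at 8.74, 1.41 and 1.26%. In SKBR-3 CM 1 the quartiles of interferon members (7.80 to 40.6%) overlap those of the markers (6.68 to 10.4%), so within that library the values do not argue against it for interferon members. For glycolysis members in MCF-7 CM the ratio of 1.18 argues the same way, but their ratio of library 2 to library 1 (0.933, quartiles 0.687 to 1.12) overlaps that of the markers (0.511 to 0.707), so carcinoma RNA cannot be told apart there for part of the rise. In MD-468 CM the markers hardly differ between libraries (0.913, against 1.05 for NF-kB members), so there it cannot be told apart either, and interferon and glycolysis members were not tested in that medium; RNA from SKBR-3 cells was not tested as a source in SKBR-3 CM. A response of the myotubes to the media stays open as a hypothesis, and whether the vehicle was unconditioned medium is not stated.

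Last come the small rises of ribosomal, oxidative phosphorylation and proteasome genes, weighed against the trend of the changes with gene length (Spearman 0.0055 in MCF-7 CM, −0.330 in MD-468 CM and −0.264 in SKBR-3 CM). Among 10000 random lists matched on length and expression, the median change lies at percentile 52.4 for ribosomal genes in MCF-7 CM, 92.2, 94.7 and 20.2 for ribosomal, oxidative phosphorylation and proteasome genes in MD-468 CM, and 94.0, 20.5 and 69.7 for ribosomal, oxidative phosphorylation and proteasome genes in SKBR-3 CM, all inside the range of such lists. The random lists leave out members of the fixed gene lists, but not other ribosomal, oxidative phosphorylation or proteasome genes. They are matched on expression too. In MCF-7 CM, almost without a length trend, lists matched to the ribosomal genes still have a median change of 0.11. These percentiles therefore cannot separate gene length from a change shared by such genes. Removing the trend brought the ribosomal median in MD-468 CM from 0.23 (quartiles 0.19 to 0.29) to 0.08 (0.04 to 0.14, limma camera adjusted p = 0.080). Oxidative phosphorylation there went from 0.20 (0.13 to 0.27) to 0.10 (−0.01 to 0.15, limma camera adjusted p = 0.22). Proteasome genes went from 0.13 (0.08 to 0.23) to 0.08 (0.01 to 0.12, limma camera adjusted p = 0.25). In SKBR-3 CM oxidative phosphorylation went from 0.13 (0.06 to 0.25) to 0.07 (−0.05 to 0.15, limma camera adjusted p = 0.38). These calls ended, with lower medians. In MCF-7 CM the ribosomal median went from 0.12 (−0.03 to 0.22) to 0.10 (−0.05 to 0.22; 0.22), a call near the threshold that ended with little change in size, while in SKBR-3 CM ribosomal (0.22, 0.15 to 0.31, to 0.12, 0.03 to 0.20; 0.0086) and proteasome genes (0.17, 0.12 to 0.23, to 0.13, 0.03 to 0.21; 0.018) still passed, and length cannot be told apart from another cause there. A difference in fragment length or RNA integrity between libraries may explain the trend; GC content also tracks the changes (Spearman −0.349, −0.0046 and −0.236), and a regulated rise of these genes stays open.

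On the mean of the media, 3 list calls ended in some fits, and why they ended was not tested. Oxidative phosphorylation genes (12 of 42 higher) had a limma camera adjusted p = 0.016. It was 0.48 with the length trend removed, 0.25 without control 1 and 0.071 without MCF-7 CM 3. Proteasome genes (5 of 30 higher) had a limma camera adjusted p = 0.0057, and 0.090 with the length trend removed. For autophagy genes (10 of 38 higher, 1 lower) the limma camera adjusted p was 0.036. It was 0.105 without control 1, 0.088 without MCF-7 CM 3 and 0.058 without MD-468 CM 2. With an estimated correlation these 3 lists had a limma camera adjusted p = 0.83, 0.73 and 0.43.

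Other splits of the samples into groups of the same sizes were run for every contrast. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05; the real split gave 3639, 3456, 2421, 1358 and 1295 genes for MCF-7, MD-468 and SKBR-3 CM against control, MD-468 against MCF-7 CM and SKBR-3 against MD-468 CM, and the highest other split 0 in each. For SKBR-3 against MCF-7 CM 2 of 10 splits gave as many genes as the real one: the real count was 315 and the highest other 1659, for MCF-7 CM 3, SKBR-3 CM 1 and SKBR-3 CM 2 against the rest, which points to a structure of the samples. For 3 controls against 9 CM libraries, fitted as a single group and so not the fit that gave 4134, the real split gave 2897 genes. Among 100 splits drawn from 220, only the real one reached this, and the highest other gave 2066. Every other split puts control and CM libraries together, so any real effect adds to the spread and lowers the count. Libraries that may share a batch are also not interchangeable, so these splits cannot exclude chance. The 2066 set MCF-7 CM 2, MD-468 CM 3 and SKBR-3 CM 3 apart. Each has the lowest TMM factor of its group (0.982, 0.985 and 0.986), as has control 1 (0.999). These 3 deviate from their group means together (r from 0.38 to 0.44 across genes), and control 1 deviates with them (0.30, 0.35 and 0.25). A batch across all 4 groups, which the labels do not give, may lie behind this; without the 4 libraries MD-468 against MCF-7 CM rose from 1358 to 2672 genes while SKBR-3 against MCF-7 CM fell from 315 to 218, and leaving out MCF-7 CM 3, not one of the 4, gave 3117 and 807, so these counts do not single out such a batch.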
